A study of Mus musculus with 3 samples.

How the data were processed

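Nuclei came from tissue dissected as the lateral habenula (LHb), a small epithalamic region, of mothers, virgin females and virgin males. Per the labels' protocols, the LHb was dissected from coronal brain sections of 1250 µm, nuclei were released in a detergent buffer, passed through a 30 µm strainer and sorted by flow cytometry for green fluorescence. The label KASH-GFP+ BNST LHb names the sorted nuclei. KASH-GFP is green fluorescent protein tethered to the nuclear envelope, and BNST is the bed nucleus of the stria terminalis. How the fluorescent label reached the neurons is not given in the sources used here. Per the labels' protocols, 3 mice were used per group, a suspension holding 1000 nuclei per group was loaded in a separate lane of the 10x Chromium 3′ assay, and the expected depth was 250000 reads per nucleus. There was thus 1 library per group.

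The authors deposited a table of unnormalised UMI counts per gene and nucleus for all 3 libraries together, where a UMI (unique molecular identifier) marks a single captured transcript. The authors also deposited a metadata table per nucleus with the library's group, total UMI count, number of genes with a UMI, percent of UMIs in mitochondrially encoded genes, broad cell class, a medial or lateral habenula label, subtype labels of a pair of LHb schemes and a cluster number. Per the submitters' processing notes, reads were processed with Cell Ranger 5.0.1, with GRCm38 (mm10) named as the genome build. Per the file headers, the metadata came from Seurat with SCTransform columns. Whether intronic reads were counted, the filters on nuclei, how doublets were treated and the reference data of the subtype schemes are not given in the sources used here. Intron counting changes how many UMIs long genes receive in nuclei, so levels of long and short genes should not be set side by side.

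Nuclei carry no common name in the deposited count table and metadata. The tables were joined by the pair of total UMIs and genes with a UMI, which was unique and present in both for all 603 nuclei. After the join, the percent of mitochondrial UMIs recomputed from the counts matched the deposited percent with a largest difference of 0. The table listed 32285 genes, of which 23009 had at least 1 UMI. The authors' classes were used as deposited, so no clustering was run, and 592 nuclei annotated as neurons entered the gene comparisons. Clusters are named by number (5 clusters), since no fixed marker class named all of them without conflict. No doublet caller was run on these small libraries, and leaving out the 5% of nuclei with most UMIs per library served as an alternative.

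Each library held 2126642 to 2790062 UMIs. UMIs of neuronal nuclei were summed per library and divided by the library's neuronal total and scaled to 1000000 to give CPM. With 1 library per group no test between groups is possible, so no p-value, standard error or count of changed genes is given, and nuclei were not treated as replicates. CPM values carry exact Poisson 95% intervals, shares carry exact Clopper-Pearson intervals, and CPM ratios (folds) carry exact conditional binomial 95% intervals. All intervals cover counting error only, and leave out variation between mice, dissections and library preparations. Those of CPM, folds and list medians also leave out variation between nuclei, since they treat UMIs as independent. A count of 0 was set against a floor of 3 UMIs. On simulated counts with known folds, intervals excluded 1 in the right direction for 62% of 100 genes at 1.5-fold and 99% of 100 genes at 3-fold for mothers against virgin females (10387 genes simulated). For virgin males against virgin females the shares were 67.4% of 95 genes and 100% of 100 (10022 simulated), and for mothers against virgin males 75.5% of 98 and 100% of 99 (9980 simulated). Intervals of genes simulated without a difference held 1 for 95.9%, 96.2% and 96.0% of genes. The simulated counts were Poisson draws, the error that the intervals assume, without variation between nuclei. These shares therefore check the computation and not how the intervals hold in real nuclei.

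The spread between a pair of libraries is the robust SD (1.4826 times the median absolute deviation) of log2 CPM ratios over genes with at least 50 UMIs in both together, with 0.5 UMI added to each sum. It is given beside the median spread of 100 simulations with counting error alone, and of 100 shuffles of neuronal nuclei between the pair of libraries. Shuffles keep the variation between nuclei and hold no difference between libraries. Before the data were examined, 24 gene lists and 13 marker classes were fixed. A list's median log2 ratio was taken over members with at least 10 UMIs in the pair and placed among 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes the libraries and is not a test of the groups. Counting intervals of medians came from 1000 Poisson draws. Standardised medians are set beside the random band of the list before standardising, since no standardised random lists were drawn. The list of ribosomal proteins was defined by the symbol's start, so it also held Rps6k kinases.

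Named genes followed a rule also fixed beforehand. Per pair, genes needed at least 50 UMIs, a UMI in at least 10% of neuronal nuclei of the library with the higher level, and the same direction after leaving out the nucleus with most UMIs of that gene from each library. Sex-linked, mitochondrially encoded, ribosomal protein and predicted genes stayed out of the ranking. Genes were ranked by the interval bound nearest to 1, and the first 10 in each direction are named. For lists, up to 4 members with most UMIs and up to 4 with the largest such bound are named, and any other member was chosen after its values were seen. A few members that the rule names are not reported here. Lists whose medians lay outside the middle 95% of their random lists, together with the hormone and opioid lists, are described with members. That choice was made after the medians were seen. The genes named within clusters follow a rule set after the data were seen (a UMI in at least 25% of the cluster's nuclei, at least 50 UMIs, at most 25% of the UMIs in 1 nucleus, 3 genes per direction), over neuronal nuclei in which no non-neuronal marker class dominated. Only part of the genes that this rule picked is given. Positions come from GENCODE release M21 on GRCm38, where 54 of 55 names looked up had a single entry.

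Alternatives were edgeR's TMM scaling, scaling without mitochondrial, ribosomal and the 50 most abundant genes, equal weight for each nucleus, all deposited nuclei, nuclei annotated LHb, standardisation to the same cluster mix, thinning of nuclei to 4780 UMIs, other minimum counts (20 and 200 UMIs for the spread, 1 and 50 for lists), 2 UMIs added, leaving out the richest nucleus of a gene, and keeping nuclei with at least 1000 UMIs and under 5% mitochondrial UMIs. Standardisation was planned over clusters with at least 20 nuclei in each library, which kept 3 clusters. Standardisation over clusters with at least 15 nuclei, which kept all 5, was added after the data were seen. So was leaving out neuronal nuclei in which UMIs of a non-neuronal marker class outnumbered those of Rbfox3, Snap25, Syt1 and Slc17a6. Thinning left out 15 nuclei of mothers, 16 of virgin females and 29 of virgin males. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. The TMM factors of the summed counts were 0.997, 1.00 and 1.00 for mothers, virgin females and virgin males.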

Results

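Transcripts were counted in single nuclei from tissue dissected as the lateral habenula (LHb) of mothers, virgin females and virgin males. The nuclei were sorted for KASH-GFP, a green fluorescent protein held at the nuclear envelope. That neurons were of the LHb is the authors' annotation, and many of their nuclei held thalamic markers, as described below. The sorted population is described by the labels as neurons of the pathway from the bed nucleus of the stria terminalis (BNST), a limbic forebrain nucleus, to the LHb, an epithalamic nucleus known for its part in aversion and negative affect. The series asks how these neurons differ with maternal experience and sex. Each group was a pool of 3 mice and gave 1 library, of 202 nuclei for mothers, 196 for virgin females and 205 for virgin males. With 1 library per group, no difference below has a replicate check, and every interval covers counting error only.

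The mothers' library held 2693450 UMIs (unique molecular identifiers, each a counted transcript), that of virgin females 2790062 and that of virgin males 2126642. The median nucleus had 11883 UMIs and 4394 genes in mothers, 12870.5 UMIs and 4507 genes in virgin females, and 9397 UMIs and 3795 genes in virgin males. UMIs per nucleus ranged from 823 to 36574 over the libraries. Malat1, a nuclear noncoding RNA, took 4.30%, 4.26% and 4.17% of the UMIs, and the 50 most abundant genes together took 20.7%, 20.5% and 20.8%. Levels are given as CPM, a gene's UMIs over the library's UMIs, scaled to 1000000. A floor of 3 UMIs corresponded to 1.11 CPM in the mothers' neuronal nuclei, 1.10 in those of virgin females and 1.41 in those of virgin males.

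Sex-linked transcripts separated the libraries along their labels. Xist (X chromosome, 103460366 to 103483254 on GRCm38), the noncoding RNA that silences an X chromosome in females, stood at 712 CPM [681, 745] in mothers and 596 CPM [567, 625] in virgin females, with a UMI in 197 of 202 and 183 of 196 nuclei. No Xist UMI was found in the 205 nuclei of virgin males, which allows up to 1.73 CPM by the exact Poisson bound. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together gave 870 UMIs in virgin males, or 409 CPM [382, 437], in 95.1% of nuclei, where the median depth was 9397 UMIs. The libraries of mothers and virgin females, whose nuclei should lack these genes, held 4 and 5 of their UMIs, in 1.49% and 2.55% of nuclei at median depths of 11883 and 12870.5. Each of the Y-linked genes was seen in males, Eif2s3y at 171 CPM, Uty at 145, Kdm5d at 53.1 and Ddx3y at 39.5, levels that gene length can set and that are not ranked here. Tsix, which lies antisense to Xist, stood at 131, 137 and 0.940 CPM, and since the strand used in counting was not given, its UMIs cannot be separated from those of Xist.

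Nearly all nuclei were annotated as neurons, 201 of 202 in mothers, 187 of 196 in virgin females and 204 of 205 in virgin males. The remaining nuclei of virgin females were 3 astrocytes, 5 ependymal cells and 1 oligodendrocyte, while mothers had 1 oligodendrocyte and virgin males 1 polydendrocyte. Among neurons, 199, 186 and 203 carried the LHb label, and 2, 1 and 1 the medial habenula (MHb) label. The neuronal nuclei fell into 5 clusters. Cluster 0 was led by Col12a1, C1ql3, Fam20a, Itga8 and Sulf1. Cluster 1 was led by Prkcq, Sox6, Man1a and Nwd2, and also by Ttr, of which only 9 of its 157 nuclei had a UMI. Cluster 2 was led by Fgf10, Kcp, Egflam and Cwh43, cluster 3 by Abhd12b, Tspear, Prkcd and Cdh4, and cluster 4 by Cpne8, Igfbpl1, Cdh9 and Megf11.

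The deposited clusters took different shares of the neuronal nuclei of each library. In mothers, clusters 0 to 4 held 23.4% [17.7, 29.9], 19.4% [14.2, 25.6], 22.9% [17.3, 29.3], 17.4% [12.4, 23.4] and 16.9% [12, 22.8]. In virgin females they held 32.6% [26.0, 39.8], 34.8% [28.0, 42.1], 13.9% [9.29, 19.7], 9.09% [5.39, 14.2] and 9.63% [5.81, 14.8]. In virgin males they held 31.4% [25.1, 38.2], 26.0% [20.1, 32.6], 12.3% [8.09, 17.6], 19.1% [14.0, 25.2] and 11.3% [7.28, 16.4]. These shares are given as a description of the libraries and not as a difference between groups, because the genes that define the clusters themselves differed between libraries (Prkcq, Sox6 and Man1a of cluster 1, Fgf10, Egflam and Heg1 of cluster 2, Cdh4 of cluster 3, Megf11 of cluster 4). The KASH-GFP sort and the lower depth per nucleus in virgin males can also set such shares.

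**Figure D1:**
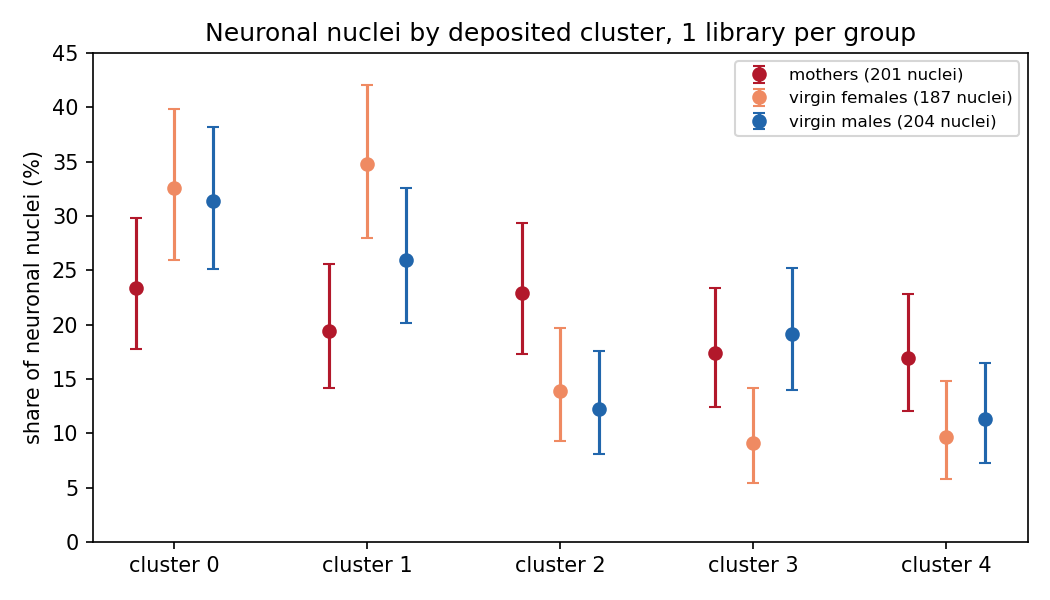
Share of neuronal nuclei (percent, vertical axis) in each deposited cluster (horizontal axis) for mothers (201 nuclei), virgin females (187) and virgin males (204), 1 library each, with bars for exact Clopper-Pearson 95% intervals. Cluster 1 held 19.4% of the mothers' nuclei, 34.8% of those of virgin females and 26.0% of those of virgin males.

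The deposited LHb subtype labels followed the clusters. In the first scheme, lhb_1 took 73.6% of neuronal nuclei in mothers, 68.4% in virgin females and 61.8% in virgin males, lhb_3 took 21.4%, 28.3% and 33.3%, lhb_2 took 0.995%, 0.535% and 0.490%, and lhb_4 took 3.98%, 2.67% and 4.41%. Cluster 0 was 86.6% lhb_3, while clusters 1 to 4 were 85.4%, 87.6%, 96.7% and 98.7% lhb_1. In the second scheme, LHb1 took 48.3%, 48.1% and 54.4%, LHb2 took 41.8%, 37.4% and 30.4%, and LHb4 took 9.95%, 14.4% and 15.2%. Cluster 1 was 54.8% LHb2 and 45.2% LHb4, and cluster 4 was 94.7% LHb2.

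Markers of thalamic neurons were abundant in nuclei annotated as LHb and differed between clusters. Summed over Lef1, Prkcd, Rora, Ntng1, Gbx2 and Plekhg1, thalamic markers stood at 7089 CPM in cluster 0, 2053 in cluster 1, 8266 in cluster 2, 10641 in cluster 3 and 1454 in cluster 4. In the mothers' library, Ntng1 and Rora gave most of this sum, with 3228 and 2271 of 6437 CPM. They had a UMI in 84.1% and 96.5% of its neuronal nuclei, so the sum mostly follows these broadly seen genes. Summed LHb markers (Gap43, Pcdh10, Htr2c, Gpr151, Pou4f1 and Chrm3) stood at 899, 1893, 1116, 1173 and 1760.5 CPM in clusters 0 to 4. Gene length can set such sums, so the marker classes are not set against each other. Prkcd, a protein kinase C used as a marker of thalamic relay neurons, reached 536 CPM in cluster 3 and 189 in cluster 2 against 13.4, 9.69 and 1.29 CPM in clusters 0, 1 and 4. Lef1, a transcription factor of the Wnt pathway, stood at 234, 40.5, 582, 727 and 16.7 CPM in clusters 0 to 4. Pou4f1, a transcription factor of habenular neurons, was seen in cluster 1 at 27.9 CPM and cluster 4 at 7.73 CPM, and gave no UMI in clusters 0, 2 and 3. Those clusters held 172, 97 and 91 of the 592 neuronal nuclei. Gpr151, a receptor used as a habenular marker, stood at 11.6, 14.8, 4.40, 0 and 1.29 CPM. Markers of GABAergic neurons were low, with 74.1 CPM in cluster 1, 126 in cluster 4 and 8.32 or less elsewhere.

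**Figure D2:**
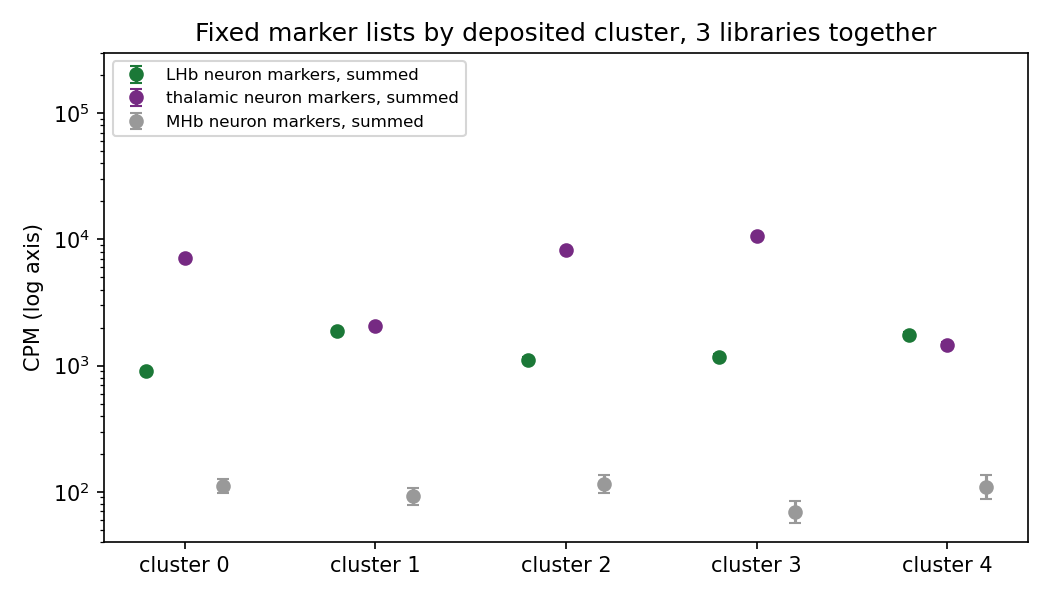
Summed CPM (vertical log axis) of the LHb, thalamic and MHb marker classes in the neuronal nuclei of each deposited cluster (horizontal axis), 3 libraries together, with bars for exact Poisson 95% intervals. Thalamic markers ranged from 1454 CPM in cluster 4 to 10641 CPM in cluster 3.

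Between libraries, LHb markers summed to 1088 CPM in mothers, 1361 in virgin females and 1534 in virgin males, thalamic markers to 6437, 5827 and 6536, and MHb markers to 107, 93.8 and 95.2. Pan-neuronal markers stood at 25029, 25973 and 25095 CPM, cortical or hippocampal markers at 148, 125 and 128, and GABAergic markers at 32.3, 37.9 and 27.8. Of the glial and vascular classes, astrocyte markers gave 283, 284 and 260.5 CPM, microglial markers 217, 184 and 199.7, oligodendrocyte markers 48.7, 60.7 and 52.3, endothelial markers 6.32, 7.36 and 7.54, and pericyte or fibroblast markers 4.46, 0.736 and 2.36. Markers of oligodendrocyte precursors gave 33.1, 93.8 and 87.1 CPM, a sum that includes the cluster 1 gene Sox6. Ependymal or choroid markers gave 2.23 and 1.10 CPM in mothers and virgin females and 351 CPM in virgin males. In that library, 5 nuclei of cluster 1 held 721 of the 735 UMIs of Ttr, the transthyretin gene of the choroid plexus. Slc17a6, the vesicular glutamate transporter of habenular and thalamic neurons, stood at 342, 366 and 353 CPM.

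Mothers and virgin females were compared to ask how the neurons differ between females with and without maternal experience. The mothers' library had higher levels of Mir670hg, a long noncoding RNA (chromosome 2, 94160636 to 94264918), with 127 CPM against 44.1 (2.89-fold [2.34, 3.58]), in 4 of 5 clusters. Prdm8, a transcriptional regulator of neuronal development (chromosome 5, 98167198 to 98188991), stood at 58.3 against 22.8 CPM (2.56-fold [1.89, 3.49]) and was higher in mothers in 5 of 5 clusters. As a list, immediate early genes, which neurons switch on within minutes of activity, were lower in the mothers' library, as were the serotonin receptor Htr2c and several heat shock genes. Ghr, the growth hormone receptor (chromosome 15, 3317760 to 3583492), stood at 16.7 CPM in mothers and 40.8 in virgin females (0.409-fold [0.283, 0.584]). In cluster 1, without the nucleus of mothers dominated by non-neuronal markers, Ghr gave 9 UMIs in mothers and 73 in virgin females. That cluster held 19.4% of the mothers' nuclei and 34.8% of those of virgin females, so the Ghr fold is not shown to hold outside it. Over 10388 genes with at least 50 UMIs, the spread of log2 ratios was 0.27. Counting error alone gave 0.19, and nuclei shuffled between the libraries gave 0.22 (range 0.21 to 0.24). Across genes, log2(CPM + 1) correlated with Pearson's r of 0.976, genes not being independent replicates.

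Further genes named by the size rule as higher in mothers were Slc17a7, the vesicular glutamate transporter of cortical and MHb neurons, with 34.9 against 12.5 CPM (2.79-fold [1.87, 4.26]), Adamts19, a secreted metalloprotease, with 63.2 against 27.2 (2.32-fold [1.76, 3.09]), and Shcbp1l with 19.3 against 6.99 (2.76-fold [1.61, 4.95]). Sox5, a transcription factor of neuronal differentiation, stood at 224 against 124 CPM (1.82-fold [1.59, 2.08]), with a log2 ratio of 0.86 that was 0.81 when standardised over clusters 0 to 2 and 0.42 over all 5. The log2 ratio of Adamts19 was 1.21, and 0.62 in nuclei thinned to the same depth. That of Slc17a7 was 1.47 in all neuronal nuclei, 2.25 when standardised over clusters 0 to 2 and 1.18 over all 5, and cluster 2 held 35.1% of its UMIs. Heg1, a membrane protein known from heart and vessel development, gave 43.8 against 13.2 CPM (3.31-fold [2.26, 4.95]), Fgf10, a secreted fibroblast growth factor, 76.2 against 31.3 (2.44-fold [1.88, 3.17]), and Egflam, a matrix protein known from photoreceptor synapses, 20.8 against 6.62 (3.14-fold [1.82, 5.68]). Heg1, Fgf10 and Egflam are genes that define cluster 2, which held 68.6% of the Fgf10 UMIs. Golga3, a Golgi protein, gave 118 against 45.2 CPM (2.60-fold [2.11, 3.23]), but its log2 ratio of 1.38 was 0.48 without the richest nucleus of each library. Standardised with those nuclei kept, it was 2.05 over clusters 0 to 2 and 1.72 over all 5.

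Among the genes lower in mothers were Popdc3, a cyclic AMP binding membrane protein, with 4.09 against 20.2 CPM (0.202-fold [0.0953, 0.390]), Trim30a, an interferon-induced gene, with 5.20 against 22.4 (0.232-fold [0.120, 0.419]), and Gpr83, a G protein-coupled receptor, with 4.46 against 19.9 (0.224-fold [0.109, 0.425]). Cluster 1 held 90.4% of the Popdc3 UMIs and 88.5% of those of Gpr83, and standardising to the same cluster mix moved their log2 ratios from −2.26 to −1.60 and from −2.11 to −1.40. Trhde, the ectoenzyme that breaks down thyrotropin-releasing hormone, stood at 26.4 against 79.8 CPM (0.330-fold [0.249, 0.434]). Ube2cbp gave 11.5 against 58.5 CPM (0.197-fold [0.129, 0.291]), with a log2 ratio of −2.33 that was −0.83 without the richest nucleus of each library. Sox6, a transcription factor (30.5 against 86.8 CPM, 0.351-fold [0.270, 0.453]), Man1a, a Golgi mannosidase (48.7 against 122, 0.40-fold [0.324, 0.491]), and Prkcq, a protein kinase C (34.2 against 85.0, 0.402-fold [0.312, 0.514]), define cluster 1, which held 94%, 90.9% and 95.7% of their UMIs. Cluster 1 also held 82.6% of the UMIs of Nr4a2, an orphan nuclear receptor (12.3 against 35.3 CPM, 0.347-fold [0.226, 0.520]), and 82.8% of those of Adam12, a metalloprotease (17.8 against 46.7, 0.382-fold [0.268, 0.536]). Standardised to the same cluster mix, the log2 ratios were −0.71 for Sox6, −0.53 for Man1a, −0.52 for Prkcq, −0.93 for Nr4a2 and −0.74 for Adam12, against −1.51, −1.32, −1.31, −1.51 and −1.38 before. Over clusters 0 to 2 they were −0.39 for Prkcq and −0.61 for Nr4a2.

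**Figure D3:**
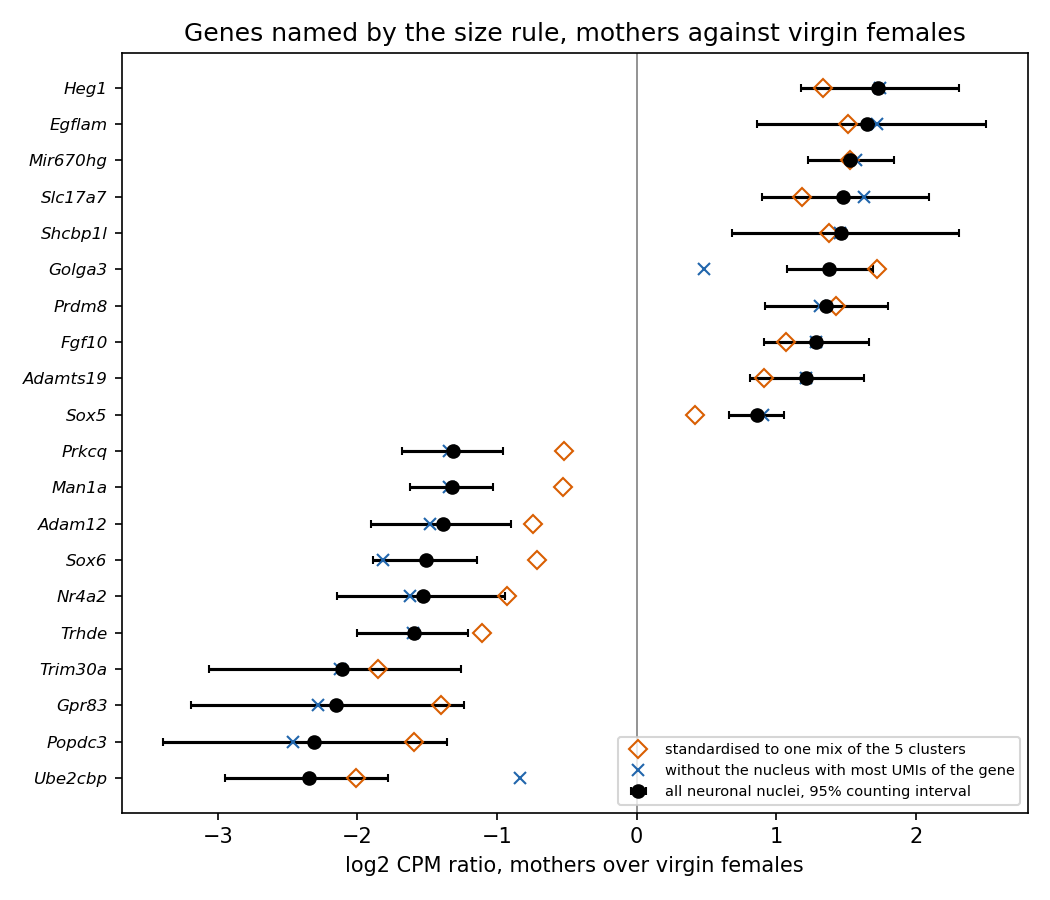
log2 CPM ratio of mothers over virgin females (horizontal axis) for the 20 genes named by the size rule (vertical axis), with 95% counting intervals, after standardising to the same cluster mix (diamonds) and without the richest nucleus of each library (crosses). Sox6 moved from −1.51 to −0.71 with standardising, and Ube2cbp from −2.33 to −0.83 without the richest nucleus.

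Immediate early genes had the lowest median of the fixed lists in this comparison, a log2 ratio of −0.74 (counting interval −0.99 to −0.31) below all 10000 matched random lists. Of 18 measured members, 10 were lower in mothers by at least 1.5-fold and 0 were higher. Fos (chromosome 12, 85473890 to 85477273) stood at 5.57 CPM in mothers and 18.4 in virgin females (0.303-fold [0.158, 0.548]), Nr4a3 at 9.29 and 23.5 (0.395-fold [0.238, 0.635]), and Fosb at 0.743 and 7.36 (0.101-fold [0.0114, 0.416], from 2 UMIs in mothers). Nr4a1 (1.05-fold [0.787, 1.41]), Homer1 (1.08-fold [0.867, 1.34]), Bdnf (1.19-fold [0.924, 1.53]) and Per1 (0.905-fold [0.658, 1.24]) had intervals that held 1. The median was −0.54 after standardising to the same cluster mix and −0.25 over the 13 members that kept 10 UMIs in nuclei thinned to the same depth, inside the random band of −0.36 to 0.33 for thinned lists. Over the same 18 members it was −0.57 in thinned nuclei.

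**Figure D4:**
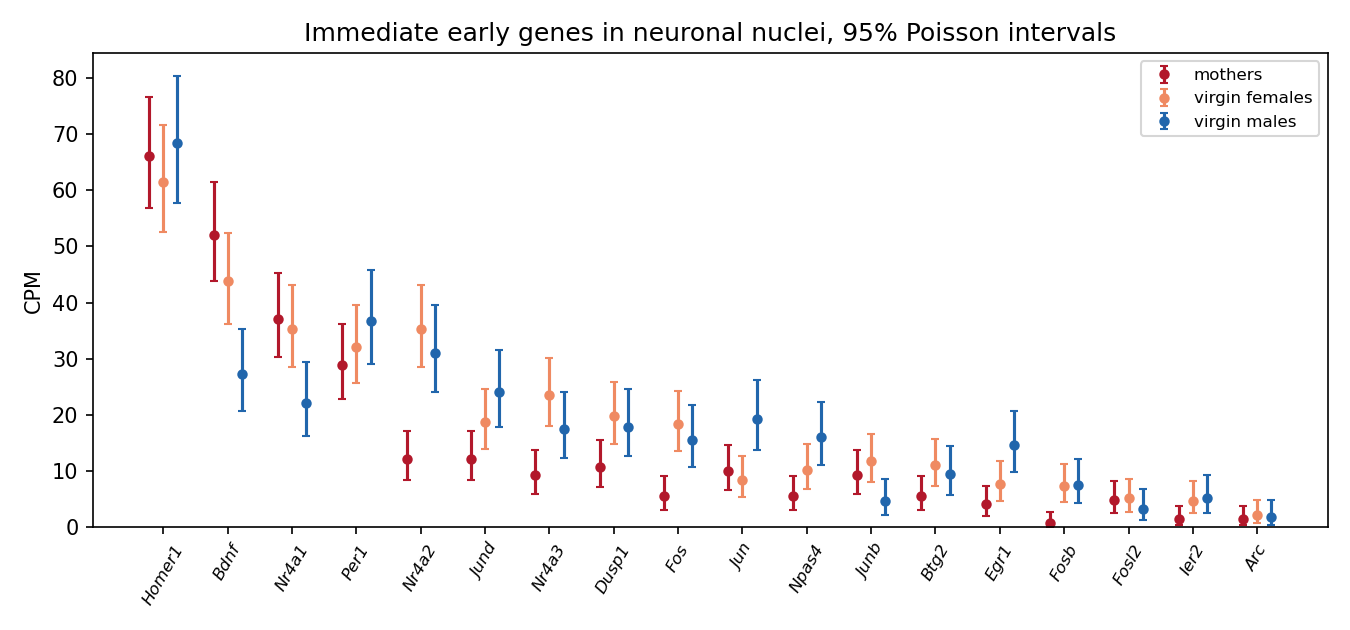
CPM (vertical axis) of the immediate early genes (horizontal axis) in the neuronal nuclei of mothers, virgin females and virgin males, 1 library each, with bars for exact Poisson 95% intervals. Fos stood at 5.57, 18.4 and 15.5 CPM, while Homer1 stood at 66.1, 61.4 and 68.3.

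Heat shock genes had a median of −0.35 (0.03 percentile of matched random lists), with none of 7 members past 1.5-fold. The chaperones Hsp90aa1 (0.712-fold [0.609, 0.831]), Hsp90ab1 (0.739-fold [0.638, 0.857]), Hspa8 (0.785-fold [0.650, 0.947]) and Hspa5 (0.808-fold [0.703, 0.929]) were lower in the mothers' library, and Hspa4l stood at 1.15-fold [0.985, 1.33]. Serotonin, dopamine and acetylcholine receptors had a median of −0.27 (percentile 0.45), with 5 of 18 members lower by at least 1.5-fold. Htr2c (X chromosome, 146962513 to 147197277) stood at 314 CPM in mothers and 523 in virgin females (0.599-fold [0.550, 0.653]), and the serotonin receptors Htr1f (0.497-fold [0.363, 0.676]), Htr2a (0.555-fold [0.314, 0.957]) and Htr4 (0.698-fold [0.514, 0.943]) were also lower. Htr7 (1.13-fold [0.958, 1.34]) and the muscarinic receptors Chrm2 (1.17-fold [1.02, 1.36]) and Chrm3 (1.00-fold [0.919, 1.09]) were not. The median of this list was −0.42 when standardised over clusters 0 to 2 and −0.13 over all 5, the last inside the random band of −0.20 to 0.19. It was 0.01 when members with at least 1 UMI were kept, so it rests on which members are measured.

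Neuropeptide and prohormone genes had a median of −0.17 (percentile 2.03), with 1 member higher and 2 lower by at least 1.5-fold of 15. The granin Chgb (0.680-fold [0.593, 0.780]), the convertase chaperone Scg5 (0.849-fold [0.766, 0.940]) and the convertase Pcsk2 (0.938-fold [0.896, 0.983]) were lower in mothers, while Scg2 stood at 0.947-fold [0.824, 1.09] and Cpe at 1.01-fold [0.925, 1.10]. Sst, the somatostatin gene, gave 21 UMIs in 1.49% of the mothers' nuclei and 1 UMI in virgin females (21.2-fold [3.41, 877]). Tac2, the neurokinin B gene and a marker of MHb neurons, gave 3 UMIs in 2 nuclei of mothers and 14 in 2 of 187 nuclei of virgin females (0.216-fold [0.0399, 0.775]), all in cluster 1, so its ratio rests on a few nuclei. Genes of synaptic vesicle release had a median of −0.14 (percentile 0.62; 2 of 22 lower by at least 1.5-fold). Cplx2, a complexin that clamps vesicle fusion, stood at 0.495-fold [0.297, 0.806], Syt4 at 0.784-fold [0.682, 0.900] and Syt2, a fast calcium sensor of which cluster 1 held 88.4% of UMIs, at 0.635-fold [0.498, 0.806]. Rims2, an active zone scaffold (1.26-fold [1.21, 1.31]), and Snap25 (1.12-fold [1.05, 1.19]) were higher in mothers, Syt1 stood at 1.02-fold [0.981, 1.05] and Rims1 at 1.04-fold [0.998, 1.08]. The Syt2 log2 ratio was 0.06 after standardising to the same cluster mix. The median of the synaptic vesicle list was −0.09 over clusters 0 to 2, inside the random band, and −0.1075 over all 5, at the band's edge of −0.1072.

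Hormone and opioid lists lay inside the middle 95% of their random lists. Oxytocin, vasopressin and prolactin signalling had a median of −0.27 (percentile 3.16, 5 members measured), in which Ghr was lower by at least 1.5-fold. Jak2, a kinase of cytokine and prolactin receptors, stood at 1.46-fold [1.11, 1.92], Prlr, the prolactin receptor, at 0.806-fold [0.613, 1.06], Socs2 at 1.02-fold [0.782, 1.33] and Stat5b at 0.827-fold [0.646, 1.06]. Sex steroid receptors and metabolism had a median of −0.13 (percentile 17.7, 6 members). The progesterone receptor Pgr stood at 0.746-fold [0.550, 1.01], Hsd17b12 at 1.09-fold [0.889, 1.34], and Esrrg, with 71.3% of its UMIs in cluster 1, at 0.746-fold [0.673, 0.827], a log2 ratio of −0.42 that was −0.05 after standardising to the same cluster mix. Stress hormone signalling had a median of 0.16 (percentile 89.3, 6 members), with the glucocorticoid receptor Nr3c1 at 1.24-fold [1.07, 1.43], its cochaperone Fkbp5 at 1.482-fold [1.06, 2.08], the mineralocorticoid receptor Nr3c2 at 0.846-fold [0.747, 0.959] and Sgk1 at 1.01-fold [0.860, 1.19]. Opioid signalling had a median of 0.27 (percentile 87.8, 6 members), with 2 members higher and 1 lower by at least 1.5-fold. Oprm1, the mu receptor, stood at 0.836-fold [0.726, 0.961], Oprk1, the kappa receptor, at 1.53-fold [0.967, 2.45], Oprl1 at 1.01-fold [0.663, 1.54], and Pdyn, the prodynorphin gene, at 0.168-fold [0.0183, 0.756] from 2 and 12 UMIs, in 0.995% and 2.67% of nuclei.

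Of the other lists of this comparison, synaptic adhesion had a median of −0.09 (percentile 2.67), with the neurexin Nrxn3 at 1.53-fold [1.47, 1.60] (log2 ratio 0.30 after standardising to the same cluster mix) and the leucine-rich repeat proteins Lrrtm3 and Lrrtm4 at 0.794-fold [0.717, 0.879] and 0.798-fold [0.770, 0.827]. Nuclear-encoded oxidative phosphorylation stood at −0.13 (2.79), mitochondrially encoded genes at −0.15 (2.51), and X inactivation and escape genes at 0.20 (97.8), above their random band of −0.19 to 0.19 but inside it, at 0.17, when standardised over all 5 clusters, with the translation factor gene Eif2s3x at 1.70-fold [1.15, 2.53]. GABA receptors stood at −0.04 (24.1), ionotropic glutamate receptors at −0.03 (28.7), metabotropic glutamate receptors at 0.03 (67.0), sodium channels at 0.07 (82.8), calcium channels at −0.01 (49.0), HCN and potassium channels at −0.000599 (54.6), axon guidance at −0.05 (13.6), calcium signalling kinases and phosphatases at −0.01 (45), interferon and antigen presentation at 0.07 (61.0) and ribosomal proteins at −0.03 (29.9), each number in parentheses being the percentile among matched random lists. The median of mitochondrially encoded genes was −0.40 when standardised over clusters 0 to 2 and −0.16 over all 5, but 0.39 with each nucleus weighted equally and 0.28 in thinned nuclei, so its direction was not settled. That of metabotropic glutamate receptors was −0.17 and −0.11 under the 2 standardisations. Y-linked genes had too few UMIs for a median.

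**Figure D5:**
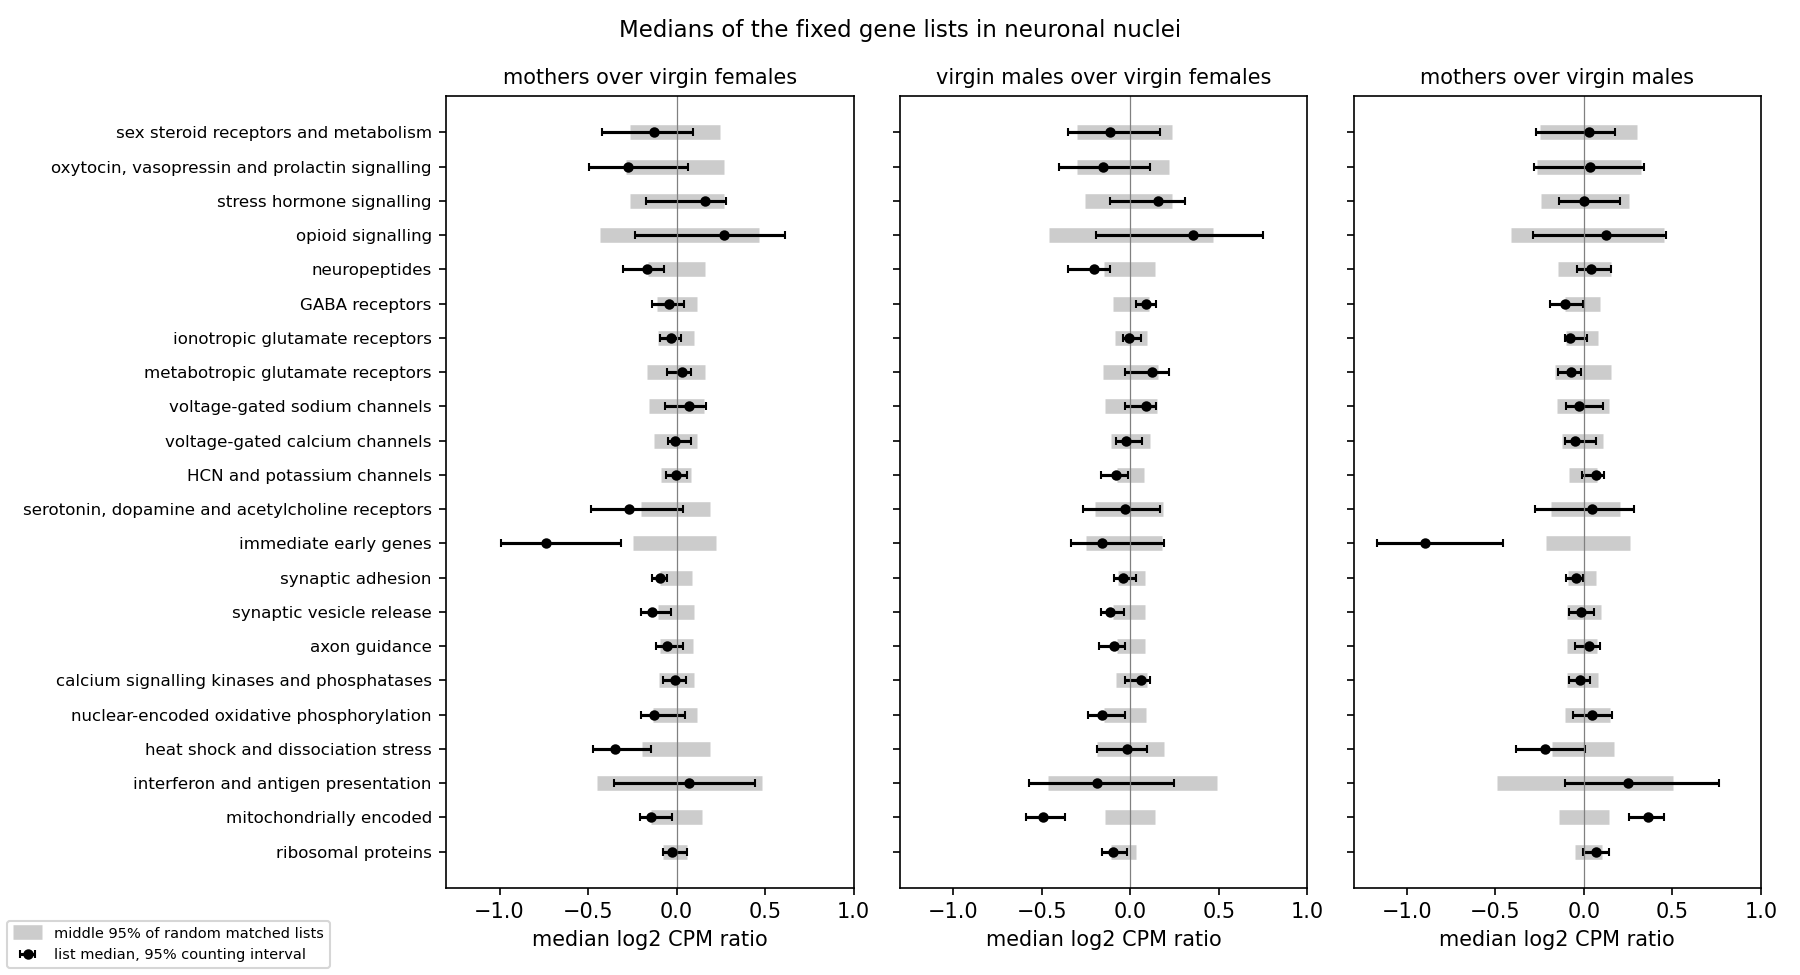
Median log2 CPM ratio (horizontal axes) of the fixed gene lists apart from the sex-linked ones (vertical axis) for each pair of libraries, with 95% counting intervals and grey bands for the middle 95% of 10000 matched random lists. Immediate early genes stood at −0.74 for mothers over virgin females, −0.16 for virgin males over virgin females and −0.90 for mothers over virgin males.

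Virgin males and virgin females were compared to ask how the neurons differ between the sexes without parental experience. The male library had lower levels of AC149090.1, a gene without a unique entry in the annotation used, with 454 against 872 CPM (0.521-fold [0.483, 0.561]) in 5 of 5 clusters, and of Htr1f, the serotonin 1F receptor, with 15.1 against 47.8 CPM (0.315-fold [0.207, 0.467]). Eln, the elastin gene (chromosome 5, 134702593 to 134747323), was higher in males with 18.8 against 3.68 CPM (5.12-fold [2.52, 11.5]), as was Chrm3, a muscarinic acetylcholine receptor, with 587 against 400 CPM (1.47-fold [1.35, 1.59]). Mitochondrially encoded genes were lower in males when UMIs were summed, though not with each nucleus weighted equally. This pair shares the library of virgin females with the comparison of mothers against virgin females. Like results in both are thus not independent and cannot be assigned to sex. Sox5, Gpr83 and Ube2cbp were named in the same direction in both, with Sox5 at 224 CPM in mothers, 226 in virgin males and 124 in virgin females. The spread of log2 ratios over 10024 genes was 0.26, where counting error alone gave 0.19 and shuffled nuclei gave 0.23 (range 0.21 to 0.25), and r was 0.969.

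Genes named as higher in males included C6, a complement component, with 115 against 52.2 CPM (2.20-fold [1.78, 2.73]), Notch2, a developmental receptor, with 20.3 against 6.62 (3.06-fold [1.73, 5.63]), Siah3 with 30.6 against 11.8 (2.60-fold [1.68, 4.11]), Angpt1, an angiopoietin, with 41.5 against 18.4 (2.25-fold [1.58, 3.26]), and Sox5 with 226 against 124 (1.83-fold [1.58, 2.10]). Sulf1, a sulfatase that leads cluster 0, stood at 90.9 against 46.4 CPM (1.96-fold [1.56, 2.47]), and Cdh4, a cadherin that defines cluster 3, at 191 against 97.1 (1.97-fold [1.68, 2.31]). The log2 ratio of C6 was 1.14 in all neuronal nuclei, 0.21 when standardised over clusters 0 to 2 and 0.63 over all 5 clusters, and that of Cdh4 was 0.98, −0.14 and 0.44 in the same order. Siah3 had a log2 ratio of 1.37 that was 0.33 in thinned nuclei, and Notch2 of 1.59 that was 0.94 without the nuclei dominated by non-neuronal markers. Enpp2, which encodes autotaxin and is abundant in choroid plexus (chromosome 15, 54838901 to 54952892), stood at 117 against 15.5 CPM (7.56-fold [5.43, 10.8]), but its log2 ratio of 2.90 was −0.21 without the nuclei dominated by non-neuronal markers. Lrriq1 stood at 18.4 against 5.89 CPM (3.12-fold [1.70, 5.98]), with a log2 ratio of 1.62 that was −0.67 over all deposited nuclei, 0.72 in thinned nuclei and 0.82 without the nuclei dominated by non-neuronal markers.

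Genes named as lower in males included Igsf11, an adhesion molecule, with 3.77 against 16.2 CPM (0.233-fold [0.0947, 0.50]), Nppc, the C-type natriuretic peptide gene, with 3.77 against 15.5 (0.244-fold [0.0989, 0.526]), Gpr83 with 5.65 against 19.9 (0.285-fold [0.139, 0.539]) and Gucy1b2, a guanylate cyclase subunit, with 4.24 against 15.5 (0.274-fold [0.117, 0.572]). Glra2, a glycine receptor subunit, stood at 19.8 against 45.2 CPM (0.437-fold [0.30, 0.625]), Ebpl at 17.9 against 40.5 (0.442-fold [0.298, 0.645]) and Nsmf, which signals from NMDA receptors to the nucleus, at 50.9 against 99 (0.514-fold [0.407, 0.645]). The log2 ratio of Ebpl was −1.16 in all neuronal nuclei, −0.64 without the richest nucleus of each library, −0.53 when standardised over clusters 0 to 2 and −1.18 over all 5. That of Nppc was −1.97 and, in thinned nuclei, −0.64. Ube2cbp stood at 17.4 against 58.5 CPM (0.298-fold [0.202, 0.428]), with a log2 ratio of −1.73 that was −0.13 without the richest nucleus of each library.

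Mitochondrially encoded genes had a median of −0.49 in males against virgin females (percentile 0), with 3 of 13 lower by at least 1.5-fold, mt-Nd3 at 0.564-fold [0.432, 0.732], mt-Co3 at 0.633-fold [0.570, 0.703], mt-Nd2 at 0.671-fold [0.590, 0.762], mt-Co2 at 0.678-fold [0.603, 0.761] and mt-Atp6 at 0.731-fold [0.661, 0.808]. With each nucleus weighted equally the median was 0.01, and over all deposited nuclei, the median percent of a nucleus's own UMIs that were mitochondrial was 0.0750% in males and 0.0496% in virgin females. Nuclear-encoded oxidative phosphorylation genes had a median of −0.16 (percentile 1.84, 22 members, none past 1.5-fold), with Cox7a2 at 0.687-fold [0.492, 0.951], Cox5a at 0.716-fold [0.522, 0.976], Atp5a1 at 0.857-fold [0.702, 1.04], Atp5b at 0.850-fold [0.693, 1.04], Cox4i1 at 0.857-fold [0.700, 1.05] and Ndufs4 at 0.877-fold [0.746, 1.03]. Standardised over clusters 0 to 2 and over all 5, that median was −0.03 and −0.02, inside the random band of −0.15 to 0.09.

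Neuropeptide and prohormone genes stood lower in males, with a median of −0.20 (percentile 0.47; 3 of 14 lower by at least 1.5-fold). The convertase Pcsk1 stood at 0.534-fold [0.359, 0.779], Pcsk2 at 0.919-fold [0.874, 0.966], Scg5 at 0.853-fold [0.764, 0.951] and Cpe at 0.980-fold [0.894, 1.07], while Scg2 was higher at 1.30-fold [1.13, 1.49]. Tac2 gave no UMI in males, against a floor of 1.41 CPM, and in virgin females 14 UMIs (5.15 CPM) that lay in 2 nuclei. Synaptic vesicle genes had a median of −0.11 (percentile 1.00; 2 of 22 lower), with Cplx1 at 0.724-fold [0.557, 0.937], Cplx2 at 0.580-fold [0.342, 0.956], Syt1 at 0.928-fold [0.892, 0.964], Snap25 at 1.05-fold [0.979, 1.12], Rims1 at 1.03-fold [0.982, 1.07] and Rims2 at 1.21-fold [1.16, 1.26]. Axon guidance genes had a median of −0.09 (percentile 1.25; 2 of 25 lower). The semaphorin receptor Nrp1 stood at 0.531-fold [0.388, 0.721] and the repellent Slit2 at 0.656-fold [0.553, 0.776], while the ephrin receptors Epha3 (1.49-fold [1.30, 1.71]), Epha7 (1.41-fold [1.23, 1.62]) and Epha6 (1.23-fold [1.16, 1.30]) were higher. Robo1 stood at 0.953-fold [0.921, 0.986], Dcc at 0.994-fold [0.940, 1.05] and Ntng1 at 1.16-fold [1.12, 1.19]. The axon guidance median was 0.04 in thinned nuclei, with the direction turned. HCN and potassium channels had a median of −0.08 (percentile 1.65), with Kcnj3 at 0.799-fold [0.717, 0.890], Kcnma1 at 0.817-fold [0.780, 0.855], Kcnc2 at 1.19-fold [1.14, 1.25], Kcnip4 at 1.14-fold [1.12, 1.15] and Kcnd2 at 1.06-fold [1.03, 1.10]. Standardised over all 5 clusters, the medians were −0.03 for synaptic vesicle release, −0.01 for axon guidance and −0.06 for HCN and potassium channels, inside their random bands. Against virgin females, mothers also had lower medians for neuropeptides (−0.17) and synaptic vesicle release (−0.14). Between mothers and virgin males these were 0.04 and −0.01, so for both lists the library of virgin females stood apart from the others. For axon guidance and for HCN and potassium channels, mothers against virgin females lay inside the random band.

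Hormone lists lay inside the middle 95% of random lists in males against virgin females too. Oxytocin, vasopressin and prolactin signalling had a median of −0.15 (percentile 20.2), with Prlr at 0.713-fold [0.523, 0.964], Socs2 at 0.897-fold [0.668, 1.20], Stat5b at 1.01-fold [0.782, 1.29] and Jak2 at 1.02-fold [0.740, 1.40]. Sex steroid receptors and metabolism had a median of −0.12 (23.8), with Pgr at 0.730-fold [0.524, 1.01], and stress hormone signalling 0.16 (91.4), with Nr3c2 at 0.778-fold [0.678, 0.893] and Nr3c1 at 1.16-fold [0.996, 1.36]. Opioid signalling had a median of 0.36 (94), which over the same members was −0.40 when standardised over clusters 0 to 2 and 0.63 over all 5, so its direction was not settled, and Pdyn gave no UMI in males and 12 in virgin females (4.41 CPM), in 2.67% of nuclei. Immediate early genes stood at −0.16 (12.6), and at 0.02 and 0.03 under the same standardisations, with 3 of 18 higher and 4 lower by at least 1.5-fold. Jun stood at 2.28-fold [1.34, 3.98], Junb at 0.40-fold [0.175, 0.834] and Bdnf at 0.624-fold [0.448, 0.861].

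For the remaining lists in males against virgin females, the medians and percentiles were 0.09 (94.5) for GABA receptors, −0.01 (43.8) for ionotropic and 0.12 (93.8) for metabotropic glutamate receptors, 0.09 (89.7) for sodium and −0.02 (36.5) for calcium channels, −0.03 (44.7) for serotonin, dopamine and acetylcholine receptors, −0.04 (11.6) for synaptic adhesion, 0.06 (90.2) for calcium signalling kinases and phosphatases, −0.02 (40.9) for heat shock, −0.19 (20.2) for interferon and antigen presentation and −0.10 (4.77) for ribosomal proteins. Y-linked genes had a median of 6.86 (percentile 100), and X inactivation and escape genes −0.35 (0.08), with Kdm5c at 0.799-fold [0.633, 1.01] and Kdm6a at 0.891-fold [0.752, 1.05]. Standardised over clusters 0 to 2 and over all 5, the median of metabotropic glutamate receptors turned to −0.08 and −0.05. The teneurin Tenm2, of the synaptic adhesion list, stood at 0.696-fold [0.673, 0.720].

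Mothers and virgin males differ in both sex and parental experience, so this pair cannot separate them. The mothers' library again had higher levels of Mir670hg, with 127 against 48.5 CPM (2.63-fold [2.10, 3.31]) and higher in 4 of 5 clusters, and of Prdm8, with 58.3 against 20.7 (2.81-fold [2.0, 4.03]) and higher in 5 of 5 clusters. Slitrk5, a synaptic adhesion protein (chromosome 14, 111675097 to 111683141), was lower in mothers, with 10.8 against 31.1 CPM (0.347-fold [0.216, 0.544]) in 5 of 5 clusters. Of 17 measured immediate early genes, 11 were lower in mothers by at least 1.5-fold and 3 were higher, and the serotonin receptors Htr2a and Htr2c were lower. Mothers share a library with the comparison against virgin females, so like results in both are not independent. The spread of log2 ratios over 9990 genes was 0.27, where counting error alone gave 0.19 and shuffled nuclei gave 0.23 (range 0.21 to 0.24), and r was 0.969.

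Other genes named as higher in mothers than in virgin males were Etv5, a transcription factor downstream of fibroblast growth factors, with 38.6 against 12.7 CPM (3.04-fold [1.97, 4.83]), Fgf1, a fibroblast growth factor, with 228 against 126 (1.80-fold [1.56, 2.09]), Usp43, a ubiquitin peptidase, with 37.9 against 15.1 (2.51-fold [1.68, 3.87]) and Ndufc1, a subunit of respiratory complex I, with 20.1 against 7.07 (2.84-fold [1.58, 5.42]). When standardised over clusters 0 to 2, the log2 ratio of Etv5 was 0.93 against 1.58 before, and that of Usp43 0.45 against 1.31, while over all 5 clusters they were 1.27 and 1.22. Fgf10 (76.2 against 33 CPM, 2.31-fold [1.75, 3.07]) and Heg1 (43.8 against 17.4, 2.52-fold [1.73, 3.74]) define cluster 2, and Megf11 (126 against 65.5, 1.92-fold [1.57, 2.36]) defines cluster 4. The log2 ratio of Fgf10 was 1.20 before standardising, 0.62 over clusters 0 to 2 and 0.70 over all 5, and that of Megf11 was 0.94, 2.19 and 0.57 in the same order. Golga3 stood at 118 against 46.6 CPM (2.53-fold [2.01, 3.20]), with a log2 ratio of 1.33 that was 0.43 without the richest nucleus of each library. Standardised with those nuclei kept, it was 2.09 over clusters 0 to 2 and 1.83 over all 5, and Golga3 was higher in mothers in 3 of 5 clusters.

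Other genes named as lower in mothers than in virgin males were Adgrv1, a large adhesion receptor, with 4.46 against 18.8 CPM (0.237-fold [0.113, 0.460]), Gulp1, an engulfment adaptor, with 77.3 against 167 (0.463-fold [0.389, 0.552]), Itpkb, an inositol trisphosphate kinase, with 11.9 against 29.7 (0.401-fold [0.253, 0.622]), Mei4 with 12.3 against 30.1 (0.407-fold [0.259, 0.628]) and Nr4a2 with 12.3 against 31.1 (0.394-fold [0.251, 0.608]). Cdh4 (78.8 against 191 CPM, 0.412-fold [0.347, 0.487]) defines cluster 3, and Sox6 (30.5 against 76.8, 0.397-fold [0.301, 0.520]) and Prkcq (34.2 against 75.8, 0.451-fold [0.345, 0.586]) define cluster 1. Enpp2 stood at 13.0 against 117 CPM (0.111-fold [0.0758, 0.159]), with a log2 ratio of −3.15 that was −0.04 without the nuclei dominated by non-neuronal markers. The log2 ratio of Cdh4 was −1.28 before standardising, −0.41 over clusters 0 to 2 and −0.85 over all 5. That of Itpkb was −1.31, −0.79 and −1.09 in the same order, and −0.78 without the richest nucleus of each library. The log2 ratio of Adgrv1 was −2.04 in all neuronal nuclei and −1.44 without the nuclei dominated by non-neuronal markers. Standardised, it was −2.90 over clusters 0 to 2 and −2.18 over all 5.

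Immediate early genes had a median of −0.90 in mothers against virgin males (counting interval −1.17 to −0.46), below all matched random lists, with 11 of 17 members lower and 3 higher by at least 1.5-fold. Egr1 (chromosome 18, 34859823 to 34864984) stood at 4.09 against 14.6 CPM (0.280-fold [0.127, 0.572]), Npas4, a transcription factor induced by neuronal activity, at 5.57 against 16.0 (0.348-fold [0.176, 0.656]) and Fosb at 0.0986-fold [0.0110, 0.419] from 2 and 16 UMIs. Bdnf (1.90-fold [1.39, 2.63]) and Nr4a1 (1.68-fold [1.18, 2.43]) were higher in mothers, while Homer1 stood at 0.968-fold [0.773, 1.21] and Per1 at 0.789-fold [0.569, 1.09]. Heat shock genes had a median of −0.22 (percentile 0.91), with Hsp90aa1 at 0.713-fold [0.605, 0.840], Hspa8 at 0.741-fold [0.608, 0.902], Hsp90ab1 at 0.833-fold [0.709, 0.979], Hspa5 at 0.915-fold [0.786, 1.07] and Hspa4l at 1.16-fold [0.986, 1.37]. The list of serotonin, dopamine and acetylcholine receptors had a median of 0.04 (63.2), with 5 members higher and 4 lower by at least 1.5-fold of 17. Htr2c stood at 314 against 532 CPM (0.590-fold [0.539, 0.645]), Htr2a at 0.457-fold [0.257, 0.792], Chrm3 at 0.682-fold [0.628, 0.740], Chrm2 at 1.64-fold [1.38, 1.95] and Htr7 at 1.16-fold [0.973, 1.39].

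GABA receptors had a median of −0.11 in mothers against virgin males (percentile 2.47; 1 of 14 lower by at least 1.5-fold). The subunits Gabra5 (0.661-fold [0.505, 0.865]) and Gabrg3 (0.694-fold [0.647, 0.744]) were lower, while Gabrb1 stood at 1.04-fold [0.987, 1.10] and Gabbr2 at 1.06-fold [0.988, 1.13]. Standardised over all 5 clusters, the list's median was −0.09, inside the random band from −0.11. Mitochondrially encoded genes had a median of 0.36 (percentile 100), with mt-Nd3 at 1.78-fold [1.37, 2.33], mt-Nd1 at 1.42-fold [1.21, 1.68], mt-Co3 at 1.38-fold [1.24, 1.53], mt-Cytb at 1.38-fold [1.20, 1.59], mt-Co2 at 1.30-fold [1.15, 1.47], mt-Atp6 at 1.29-fold [1.16, 1.42] and mt-Nd2 at 1.24-fold [1.09, 1.42]. When standardised over clusters 0 to 2 the median was −0.04, and over all 5 clusters 0.06, both inside the random band of −0.14 to 0.14. X inactivation and escape genes had a median of 0.87 (percentile 100), with Eif2s3x at 2.01-fold [1.29, 3.21], Ddx3x at 1.68-fold [1.25, 2.27], Kdm5c at 1.37-fold [1.09, 1.72] and Kdm6a at 1.15-fold [0.969, 1.36], and Y-linked genes had a median of −7.88 (percentile 0).

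Hormone lists in mothers against virgin males had medians of 0.04 for oxytocin, vasopressin and prolactin signalling (percentile 50.4), 0.03 for sex steroid receptors and metabolism (51.6), 0.00285 for stress hormone signalling (52.1) and 0.13 for opioid signalling (75). Within them Ghr stood at 0.486-fold [0.328, 0.715], Jak2 at 1.43-fold [1.07, 1.92], Prlr at 1.13-fold [0.824, 1.56] and Pgr at 1.02-fold [0.722, 1.45]. The remaining medians were 0.04 (69.9) for neuropeptides, −0.08 (7.52) for ionotropic and −0.07 (19.9) for metabotropic glutamate receptors, −0.02 (38.2) for sodium and −0.05 (22.9) for calcium channels, 0.07 (97.1) for HCN and potassium channels, −0.04 (18.6) for synaptic adhesion, −0.01 (38.4) for synaptic vesicle release, 0.03 (76.1) for axon guidance, −0.02 (38.3) for calcium signalling kinases and phosphatases, 0.05 (66.6) for nuclear-encoded oxidative phosphorylation, 0.25 (83.4) for interferon and antigen presentation and 0.07 (89.1) for ribosomal proteins.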

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

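Every test in this part was chosen after the values it bears on had been seen, apart from the thinning of nuclei, which was planned, and the standardisation by cluster and subtype, which was written down before its result; the bounds that decide the tests of thalamic neurons, preparation stress, cluster mix and depth were also set or tightened afterwards, and values are given so that either reading can be made.

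Y-linked genes gave 4 UMIs in the library of mothers and 5 in that of virgin females, singled out because they come from genes that female nuclei lack and lie above the 3 UMIs that a count of 0 allows. Nuclei annotated as other than neurons numbered 9 in virgin females (4.59% [2.12, 8.54]), singled out because they lie outside the neuronal comparisons, against 1 each in mothers (0.495% [0.0125, 2.73]) and virgin males (0.488% [0.0123, 2.69]).

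Thalamic marker transcripts in nuclei annotated as habenular were weighed first. Free RNA from thalamic cells would give all clusters a like share of nuclei with Prkcd, whereas in nuclei thinned to 4780 UMIs the share was 92.1% [84.5, 96.8] in cluster 3 and 1.43% [0.0362, 7.70] in cluster 4, so the highest share was 11.96 times the upper bound of the lowest. Nuclei of thalamic neurons taken with the dissection might carry these markers. The sort for KASH-GFP would remove them only if they lacked the label, and how the label reached the neurons is not given. The 14 thinned nuclei with a Pou4f1 UMI had 0.236 [0.191, 0.289] of the thalamic marker level of the others. The 20 with a Gpr151 UMI had 0.701 [0.632, 0.774], a ratio that separates the nuclei far less. The level compared was the sum over the thalamic markers, of which Ntng1 and Rora gave most in each library. By Pou4f1 alone the explanation by thalamic nuclei would be met, and by Pou4f1 and Gpr151 together it stays open. Habenular neurons that themselves express the thalamic markers also stay open, since 5.96% of thinned neuronal nuclei had a UMI of either habenular marker, too few to say what the rest are. The rule could speak against this explanation only if most nuclei had such a UMI. Even at full depth, at most 8.46% of a library's neuronal nuclei had a Gpr151 UMI and at most 6.86% a Pou4f1 UMI, so it could not decide.

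For the genes named between mothers and virgin females, a different mix of clusters could set folds of genes such as Sox6 and Fgf10. Standardised to the same mix of the 5 clusters, the median log2 ratio of the 10 genes lower in mothers went from −1.55 to −1.02 [−1.299, −0.77], and that of the 10 genes higher in mothers from 1.41 to 1.35 [1.07, 1.53], both beyond 1.5-fold, with 8 and 9 genes past it. A different mix of subtypes within the clusters left −0.92 [−1.28, −0.74] for the lower genes over 7 combinations of cluster and second subtype label that covered 92.4% of nuclei. Standardising thus took away part of the lower levels and left folds in both sets, as far as the deposited clusters capture the mix. The genes were picked as the largest folds of these same counts, and several of them define the clusters. The folds left over are therefore raised by the choice of genes, and they cannot decide how much cluster mix accounts for. Differences between mice, dissections or lanes, and maternal state, were not tested and cannot be separated with 1 library per group.

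Lower immediate early genes in mothers were weighed against cluster mix, depth and preparation. Standardised to the same cluster mix, the list's median was −0.80 [−1.06, −0.40] against virgin males, below the random band from −0.22. Against virgin females it was −0.54 [−0.87, −0.21], whose interval reaches into the band from −0.25, so a different mix may carry part of that difference. Both bands are those of the list before standardising. In thinned nuclei the median was −0.25 [−0.75, 0.15] against virgin females (13 members, band from −0.36) and −0.80 [−1.06, −0.18] against virgin males (15 members, band from −0.33), so this test leaves depth per nucleus open. Thinning dropped members with few UMIs, and over the unthinned members it gave −0.57 [−1.001, −0.06] and −0.88 [−1.21, −0.29]. The median nucleus held 11883 UMIs in mothers, between 9397 in virgin males and 12870.5 in virgin females, whereas the list was lower in mothers than in both. The order of the libraries in depth was thus not their order in this list. A milder stress response during dissection and nuclei preparation is a candidate explanation that stays open, because the heat shock list was also lower, with −0.35 [−0.47, −0.14] against virgin females and −0.22 [−0.39, 0.01] against virgin males, where the medians lay below the bands from −0.20 and −0.18 but the intervals reached into them. Maternal state is confounded with the single library of mothers (1 library) and stays an untested hypothesis.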

How the results depend on the processing

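Standardisation over clusters with at least 15 nuclei and the comparison without nuclei dominated by non-neuronal markers were chosen after the data were seen, and all other alternatives were planned. Of alternative values, 592 log2 folds, 866 list medians, 18 spreads, 30 shares and 3 CPM values stayed within their intervals, and 63, 52, 18, 0 and 3 moved beyond them. The interval of a spread came from resampling genes, and those of the other values covered counting error. In addition, 5 folds turned direction, as did 5 medians of lists outside the middle 95% of their random lists. For lists inside it, 93 alternative medians, counted above among those within or beyond counting error, also had the other sign, 18 of them beyond their counting intervals, so no direction is read from these lists. The cause was not tested unless named. The spreads of 0.27, 0.26 and 0.27 (mothers against virgin females, virgin males against virgin females, mothers against virgin males) became 0.320, 0.301 and 0.305 with each nucleus weighted equally, 0.305, 0.297 and 0.320 when standardised over clusters with at least 20 nuclei, 0.317, 0.301 and 0.297 in thinned nuclei, 0.311, 0.302 and 0.312 over genes with at least 20 UMIs, and 0.208, 0.194 and 0.192 with at least 200 UMIs. The last 3 settings also moved the counting error alone, to 0.240, 0.240 and 0.242 when thinned, 0.223, 0.234 and 0.236 at 20 UMIs, and 0.124, 0.127 and 0.127 at 200. Mothers against virgin females gave 0.276 over all deposited nuclei, and 0.276 without the top 5% of nuclei by UMIs, as did mothers against virgin males. Keeping members with at least 1 UMI turned the median of serotonin, dopamine and acetylcholine receptors in mothers against virgin females to 0.00759. Standardised over clusters with at least 20 nuclei, axon guidance in virgin males against virgin females turned to 0.0306, mitochondrially encoded genes in mothers against virgin males to −0.0389, and Cdh4 in virgin males against virgin females to −0.14, where cluster 3, which Cdh4 defines, was left out. Weighting each nucleus equally turned mitochondrially encoded genes in virgin males against virgin females to 0.00845. In thinned nuclei, axon guidance in that pair turned to 0.0408, Enpp2 to −1.15 and, in mothers against virgin males, to 0.65, while Xist gave 776 CPM in mothers and 660.2 in virgin females, and Y-linked genes gave 0 CPM in mothers. Without nuclei dominated by non-neuronal markers, Enpp2 in virgin males against virgin females turned to −0.21, and over all deposited nuclei Lrriq1 turned to −0.67. Cluster resolution and the number of principal components were not varied, because the authors' annotation was used. No paired analysis was possible because each group had 1 library, and no library could be left out. Depth limits genes near 3 UMIs, and lists of few UMIs such as immediate early genes.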

Other observations

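The genes below are part of those picked by a rule set after the data were seen, as leading differences between libraries within a cluster. They were chosen among these after their values were seen, without a further rule, and are values without a test. The neuronal nuclei in which non-neuronal markers dominated, 1 of mothers and 5 of virgin males, all in cluster 1, were left out of these values. In cluster 0, Mir670hg stood at 227 CPM in mothers, 35.5 in virgin females and 41.5 in virgin males (6.41-fold [4.33, 9.76] and 5.48-fold [3.60, 8.66]), and in cluster 3 at 6.64-fold [3.83, 12.3] in mothers against virgin males. Nrg1, a growth factor of the neuregulin family, stood at 0.501-fold [0.433, 0.578] in cluster 0 of mothers against virgin females. Opcml, an adhesion molecule, was lower in virgin males than in virgin females in cluster 0 (1069.5 against 2371 CPM, 0.451-fold [0.413, 0.492]) and in cluster 3 (0.414-fold [0.367, 0.466]), as was the phosphodiesterase Pde7b in cluster 0 (0.344-fold [0.264, 0.443]). In cluster 3, the ephrin receptor Epha5 stood at 0.280-fold [0.197, 0.389] and the glycosyltransferase Galnt14 at 4.08-fold [2.90, 5.87] in mothers against virgin males, and Adamts19 gave 48 UMIs in mothers and 3 in virgin females (9.99-fold [3.22, 50.1]).

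Cluster 1 differed between virgin females and both other libraries in Adarb2, a member of the RNA-editing deaminase family, with 290.0 CPM against 65.5 in mothers (0.226-fold [0.148, 0.332]) and 65.5 in virgin males (0.226-fold [0.148, 0.333]). Within the same cluster Ghr stood at 0.236-fold [0.104, 0.473] and the cation channel Trpm3 at 2.07-fold [1.84, 2.33] in mothers against virgin females, while in cluster 4 Trpm3 stood at 0.596-fold [0.513, 0.692], the other direction. Kirrel3, a synaptic adhesion molecule, gave 1052 CPM in cluster 1 of mothers and 226 in that of virgin males (4.66-fold [3.74, 5.84]), and Chrm3 was higher in virgin males than in virgin females there (1.75-fold [1.53, 2.01]). In cluster 2, Nrp2, a semaphorin receptor, gave 47 UMIs in mothers and 3 in virgin females (11.5-fold [3.71, 57.9]). Col25a1, a membrane collagen, was lower in cluster 4 of mothers (0.454-fold [0.3005, 0.686]) and of virgin males (0.227-fold [0.107, 0.441]) than of virgin females. Clusters held as few as 17 nuclei of a library, so single animals of the pool can weigh heavily in these values. Cluster 1 was also mixed, with 86 LHb2 and 71 LHb4 nuclei. It held 39, 65 and 53 nuclei of mothers, virgin females and virgin males, while LHb4 numbered 20, 27 and 31 over all their neuronal nuclei. These values were not standardised by subtype, so differences within cluster 1 cannot be told apart from a different subtype mix.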
